A study of Mus musculus with 3 samples.

How the data were processed

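RNA from mouse heart tubes at embryonic day 9.5 was measured in 3 libraries, 2 from Sox7-null and 1 from wild-type tubes, grouped by the genotype in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded total RNA kit, which does not select polyadenylated transcripts. The protocol text names retinal organoids as the source, whereas the tissue label names the heart tube. The tissue label was followed here, and retina and heart markers were both examined. The deposited values are whole-number read counts per gene symbol, 1 library to a file and not pooled, with 23337 genes and 5 summary lines per file, as the files themselves show. Per the submitters' processing notes, CASAVA, TopHat2, HTSeq and DESeq2 1.10.1 were used, with no versions for the first 3. The same notes name the human builds hg19 and GRCh37, while the gene symbols are those of mouse, so the build behind the counts is not settled and no coordinates are printed. The annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and an overlapping or antisense gene therefore cannot be told apart, and genes with near-identical copies are uncertain.

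The 5 summary lines were left out of library sizes and tests. They held reads with no feature (8.10%, 8.52% and 11.7% in Sox7-null 1, Sox7-null 2 and the wild type), ambiguous reads (2.27%, 2.29% and 1.97%) and reads that were not uniquely aligned (10.4%, 11.6% and 22.3%), and 0 reads of low quality or not aligned. The files held 16590715, 17540851 and 21523795 reads in all. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was 20.7 between the null libraries and 124 and 75.4 between each of them and the wild type, so all 3 were counted as separate samples. Of the symbols, 21158 were current in GENCODE M21 or RefSeq GRCm38, 1977 were older symbols and 202 matched neither.

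The comparison of Sox7-null with wild type was tested on the deposited counts with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. TMM normalization gave factors of 1.03, 1.01 and 0.962. The filterByExpr filter, with a minimum count of 10, left out 10003 genes and kept 13334. The model had the genotype as its term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. With 2 libraries against 1 there was 1 residual degree of freedom, supported by 11.8 prior degrees of freedom, and the lone wild-type library was assumed to vary like the null libraries. The biological coefficient of variation was 15.0%. The labels give the libraries no shared replicate numbers, so no pairing was used. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The median log2 fold change of all tested genes was 0.014, and other scalings moved it by under 0.1. A separate rule without a test counted genes with a difference of at least 1 in log2(CPM + 0.5), TMM-scaled, in the same direction in both null libraries and a mean of at least 5 CPM.

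Before the data were examined, 37 gene lists were fixed for cell types, pathways and stress responses that heart tubes or neighbouring tissue could show. Of 836 entries, 804 matched a symbol in the files, 14 of them through an older symbol. The 36 lists with at least 3 tested genes are reported, and the list of mitochondrially encoded genes had no member in the files. Each list is described by its members past the threshold, over all genes and adjusted over the list alone, and by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins. Limma 3.58.1's camera was run with a preset correlation of 0.01, which called 14 lists at an adjusted p under 0.05, and with an estimated correlation, which called 0. The smallest p with an estimated correlation was 0.0976 before adjustment, for ribosomal protein genes. With an estimated correlation the test rests on the 1 residual degree of freedom, so a list could hardly pass. Its 0 calls therefore decide nothing for or against a list, and the preset correlation is an assumption that these libraries cannot check.

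The genes named in the text also followed a rule fixed before the data were examined. It took Sox7, Sox17, Sox18, Wnt4 and Bmp2, the 10 genes with the largest changes up and the 10 down among those past the threshold with a mean of at least 5 CPM and the same sign in both null libraries (predicted genes and ribosomal or small nuclear RNA genes passed over), up to 4 members of each list by smallest p, and members that the description of a list needed. One gene that the rule takes is not reported here by name. A fold is given with a 95% exact interval on summed counts where a group held few reads, and as a lower bound against a floor of 3 counts over the group where it held 0. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

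The test was tried on simulated counts drawn from the means and library sizes of these samples for the comparison of Sox7-null with wild type, with 200 genes changed, of which 196 were tested among 13108. It called 51 of 97 genes changed by a log2 fold change of 1, 90 of 99 changed by 2, and 5 of 12883 unchanged genes. All 3 simulated libraries were drawn with the same trended dispersion and without a length trend. The few calls among unchanged genes therefore do not test whether the lone wild type varies like the null libraries. A simulated list raised by 0.5 lay at percentile 100 and an unchanged one at percentile 84.2. The simulated genes were drawn independently, and the random lists were drawn gene by gene. The percentiles thus take no account of correlation among list members, and the simulation does not test them for it.

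The alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, no filter on low counts, a minimum mean of 5 CPM, removal of haemoglobin, mitochondrial and ribosomal RNA genes, DESeq2 1.42.0, limma-voom, edgeR with legacy=FALSE and with robust=TRUE, glmTreat against a fold of 1.5, and leaving out each null library, which leaves 1 library against 1 and no test. Chosen after seeing the data were no filter combined with edgeR legacy=FALSE, limma-voom or DESeq2, and a fit in which a per-library loess trend (span 0.3) on transcript length and GC content was removed as an offset. The 2-fold rule without each null library was also run afterwards with the scaling of all 3 libraries kept, and the mean CPM taken over all 3 or over the 2 left. Length and GC came from the longest GENCODE M21 transcript of each gene, found for 99.1% of tested genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.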

Results

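Transcripts were measured by bulk RNA-seq in mouse heart tubes at embryonic day 9.5, when the heart is a looping tube lined by endocardium and the first trabeculae form. Sox7 encodes a transcription factor of the SoxF family that is made in endothelial cells and endocardium. The series asks which transcripts of the heart tube differ when this gene is absent. The Sox7-null group held 2 libraries and the wild-type group held 1. Reads assigned to genes numbered 13139823 in Sox7-null 1, 13618338 in Sox7-null 2 and 13789388 in the wild type, and 15884, 15854 and 16154 genes had at least 1 read. The labels do not say whether a tube came from a separate embryo or from a pool, so the p-values measure only the spread between the 2 null libraries, which may be technical. Reads of the X-inactivation transcript Xist (691, 228 and 274) and of the Y-linked gene Ddx3y (284, 927 and 443) were present in Sox7-null 1, Sox7-null 2 and the wild type alike. Each library thus appears to hold RNA of both sexes.

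Sox7 itself was low in both null libraries, with 2 and 7 reads against 222 in the wild type. This was a 50.7-fold lower level (95% exact interval for counting error 26.2 to 112) and a log2 fold change of -5.63 ± 0.47 (SE; edgeR adjusted p = 3.81e-05). Of its 2 closest relatives, Sox17 rose, by a log2 fold change of 2.38 ± 0.38 (edgeR adjusted p = 0.00140), with 14.6 and 10.6 CPM (normalised counts scaled to a common library size) in the null libraries and 2.41 in the wild type. Sox18 had a log2 fold change of -0.25 ± 0.28 (edgeR adjusted p = 0.573). The SoxF list of 3 thus had 1 gene that rose and 1 that fell, both over all genes and adjusted over the list alone. Wnt4, a Wnt ligand of the endocardium, fell, with 37 and 20 reads against 216 and a log2 fold change of -2.95 ± 0.37 (edgeR adjusted p = 0.000416). Bmp2, a ligand that induces cushion formation, had 669 and 869 reads against 1028 and did not pass the test (log2 fold change -0.46 ± 0.21, edgeR adjusted p = 0.134).

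Across the transcriptome, 36 of 37 glycolysis and hypoxia genes, 23 of 24 integrated stress response genes and all 11 platelet markers were higher in the Sox7-null heart tubes. So were 19 of 34 matrix genes, where 1 fell, and the natriuretic peptide genes Nppa and Nppb. Most liver and foregut endoderm markers and 9 of 33 cell cycle genes were lower, as were 23 of 40 ribosomal protein genes. Once a trend on transcript length and GC was removed, 3 of the 40 fell and 2 rose. Of 13334 genes tested, 1508 were higher and 1366 lower at an adjusted p under 0.05, which was 21.6% of those tested. All 2874 moved the same way in both null libraries, which the test nearly requires. Its spread comes from those 2 libraries, and both are compared with the same wild type. Among the called genes 897 were higher and 483 lower by a log2 fold change of at least 1. Of 36 gene lists, 11 had a median above the 97.5th percentile of random lists matched on expression, namely the glycolysis, stress response, platelet, immediate early, matrix, trabecular, sarcomere, epicardial, macrophage, BMP and smooth muscle lists. The foregut, erythroid, ribosomal protein, cell cycle and histone lists, 5 in all, lay below the 2.5th percentile. With the length and GC trend removed, 9 and 5 lists did. The BMP (92.8), smooth muscle (86.3), erythroid (32.9) and ribosomal protein (11.1) lists then lay inside these percentiles, and the cushion (0) and surface ectoderm (1.61) lists lay below, against 9.98 and 2.54 before. All these percentiles leave out correlation among the members of a list. The list test camera called 14 lists with a preset correlation and 0 with an estimated correlation, where the adjusted p was 0.937 or above. With 1 residual degree of freedom a list could hardly pass the latter, so its values, here and below, are not evidence against a list. Among these 16 lists, the epicardial, erythroid and macrophage medians changed sign when Sox7-null 1 was left out (-0.045, 0.23 and -0.67, against 1.18, -1.44 and 1.81 without Sox7-null 2). Outside them, the neural tube, neural crest, cardiac transcription factor and sex-linked lists had medians of opposite sign without the one and without the other null library.

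**Figure D1:**
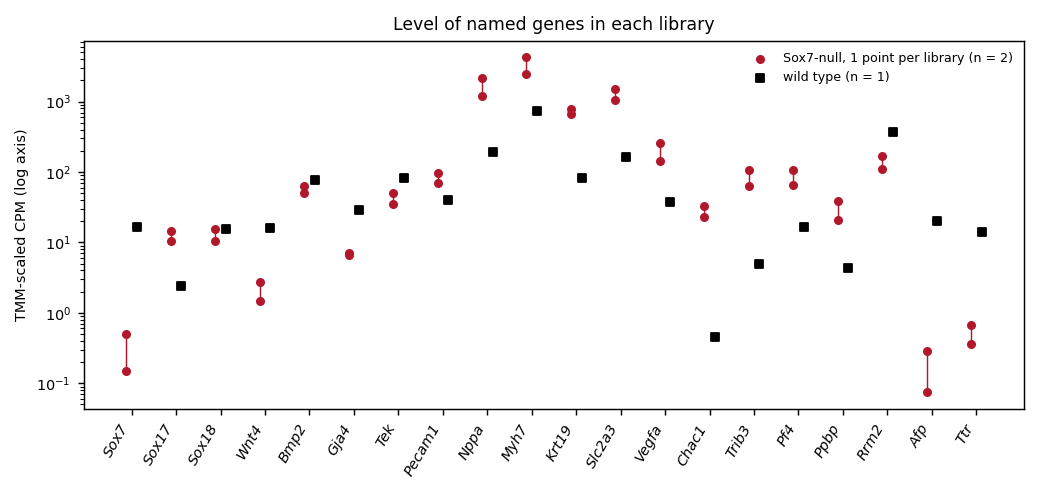
Level of 20 named genes in each library, as TMM-scaled CPM on a log axis, with a red point for each of the 2 Sox7-null libraries, a red line joining them and a black square for the single wild-type library. For Sox7 the null libraries lie far below the wild type, for Sox17 they lie above it at 14.6 and 10.6 against 2.41, and for Sox18 and Bmp2 the libraries lie close together.

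The largest increases were in genes with few reads in the wild type. Sncb, which encodes beta-synuclein, had 300 and 175 reads against 2, a 116-fold higher level (95% exact interval 31.8 to 957), and Sprr1a, a small proline-rich protein, had 134 and 88 against 1 (108-fold, 19.2 to 4284). Chac1, which degrades glutathione, rose by a log2 fold change of 5.90 ± 0.45, and Espn, an actin-bundling protein, by 5.56 ± 0.63. The cationic amino acid transporter Slc7a3 rose by 5.38 ± 0.44 (edgeR adjusted p = 3.13e-05). Stc2, Dpp6, Car9 and Adm2 rose by 4.93, 4.66, 4.43 and 4.40. At the other end, Afp, the fetal serum protein alpha-fetoprotein, had 1 and 4 reads against 271, which was 111-fold lower (95% exact interval 47.2 to 346), and the thyroid hormone carrier Ttr had 9 and 5 against 187 (log2 fold change -4.75 ± 0.43). Crabp2, which binds retinoic acid, had a log2 fold change of -2.40 ± 0.48 and did not pass with DESeq2. Pik3r3, Omd, Gpr22 and Slc7a14 had values of -2.25, -2.19, -2.16 and -2.08. Lars2 fell too, at -2.25 ± 0.13, but its level moved with that of the ribosomal RNA gene Rn45s (log2 fold change -1.48), so reads shared with ribosomal RNA leave it uncertain.

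Genes of glycolysis and the response to low oxygen rose almost as a block. Of 37 tested, 36 rose and 0 fell, and adjusted over the list alone the count was also 36. Their median log2 fold change was 1.37 (1.45 in Sox7-null 1 and 1.27 in Sox7-null 2). The glucose transporter Slc2a3 rose by 2.97 ± 0.22, the mTORC1 inhibitor Ddit4 by 3.07 ± 0.27, the collagen prolyl hydroxylase P4ha2 by 2.83 ± 0.25 and the repressor Bhlhe40 by 3.70 ± 0.35, and the exception was Pfkfb4 (edgeR adjusted p = 0.471). Genes of the integrated stress response, which act downstream of the transcription factor Atf4, showed 23 of 24 higher and 0 lower (23 adjusted over the list alone), with a median of 2.18, or 2.28 and 1.87 in the 2 null libraries. Beside Chac1, Slc7a3 and Stc2, the pseudokinase Trib3 rose by 4.10 ± 0.36, with 1450 and 870 reads against 66. Nupr1 had 31 reads in the null libraries and 0 in the wild type, at least 5.03-fold higher against a floor of 3 counts. Of 17 immediate early genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.77), among them Ier3, with 1643 and 1031 reads against 71, Junb at 2.23 ± 0.37, Atf3 at 1.73 ± 0.29 and Egr1 at 1.43 ± 0.32. All 3 lists were called by camera with a preset correlation, with adjusted p = 0.937 for each with an estimated correlation.

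Other stress genes moved both ways. Among 13 heat shock genes 3 rose and 4 fell, over all genes and adjusted over the list alone, with a median of 0.02. The mitochondrial chaperone gene Hspe1 fell, at -1.20 ± 0.15, as did Hsp90aa1, at -0.84 ± 0.14, while Hspa1a, which has a near-identical neighbour and is therefore uncertain, rose with 58 and 73 reads against 7. Of 21 p53 target and cell death genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.04). The cell cycle inhibitor Cdkn1a rose by 2.10 ± 0.34 and Sesn2 by 2.85 ± 0.32, and Ei24 fell by 0.80.

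Genes of chamber and trabecular myocardium were mostly higher. Of 19 tested, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.73, or 0.93 and 0.46 in the 2 null libraries, and 6 rose and 2 fell with the length and GC trend removed. The atrial natriuretic peptide gene Nppa had 29524 and 16516 reads against 2585 (log2 fold change 3.12 ± 0.30, edgeR adjusted p = 8.22e-05). Bmp10, a growth factor of trabecular myocardium, rose by 2.57 ± 0.31, Nppb by 1.33 ± 0.16 and the angiogenic factor Vegfa by 2.44 ± 0.32. Among 39 sarcomere and contractile genes 17 rose and 4 fell (19 and 6 adjusted over the list alone; median 0.39), and 12 and 1 with the length and GC trend removed. The heavy chain gene Myh7 rose by 2.20 ± 0.25, Actn2 by 1.12 ± 0.17, Tnnt2 by 0.88 ± 0.14 and Xirp1 by 1.21 ± 0.20. Pln, an inhibitor of the calcium pump, fell, at -0.93, and so did Myl2, at -0.57. Both lists were called by camera with a preset correlation, at adjusted p = 0.00110 each, against adjusted p = 0.937 with an estimated correlation.

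Cardiac transcription factors had no common direction, with 5 of 26 higher and 1 lower, also adjusted over the list alone, and a median of 0.05 (4 and 4 with the length and GC trend removed; median -0.05). The median was -0.02 in Sox7-null 1 and 0.13 in Sox7-null 2. Myocd, a coactivator in muscle, rose by 1.25 ± 0.21 and Mef2d by 1.30 ± 0.24, and Hand2 fell, at -0.91 ± 0.20. In the second heart field and pharyngeal list 0 of 17 rose and 1 fell (Hoxb1, with 7 reads in the null libraries against 23), and 0 passed adjusted over the list alone (median 0.10). Of 15 epicardial and proepicardial markers 5 rose and 0 fell, also adjusted over the list alone (median 0.70). These included the keratins of simple epithelia Krt19 at 3.17 ± 0.20, with 10671 and 9216 reads against 1074, Krt8 at 1.49 ± 0.18 and Krt18 at 1.36 ± 0.19, and the transcription factor Wt1 at 0.97 ± 0.24. The median of this list was 1.17 in Sox7-null 1 and -0.04 in Sox7-null 2, and Tbx18 (-0.16) and Tcf21 (-0.43) did not pass. Smooth muscle and mural cell markers included 4 of 13 that rose and 0 that fell, also adjusted over the list alone (median 0.48), but 2 and 1 with the length and GC trend removed (median 0.16), with Cnn1 at 1.11 ± 0.19 and Tagln at 0.69 ± 0.15. Camera with a preset correlation called the epicardial and the smooth muscle lists, with adjusted p = 0.937 for each with an estimated correlation.

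Endothelial and endocardial markers moved both ways. Of 34 tested, 8 rose and 4 fell (10 and 6 adjusted over the list alone; median 0.12), but 3 and 5 with the length and GC trend removed (median 0.03). The adhesion molecule Pecam1 rose by 1.07 ± 0.24, whereas the orphan receptor Gpr182 fell, at -1.38 ± 0.23, and the angiopoietin receptor Tek fell, at -0.91 ± 0.23. Of 12 arterial markers 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.33), but 1 and 2 with the length and GC trend removed (median 0.16). Gja4, the connexin of arterial endothelium, fell, at -2.08 ± 0.24 (edgeR adjusted p = 0.000311), as did Bmx, at -1.40 ± 0.40. Of 7 venous and lymphatic markers 2 rose and 0 fell, also adjusted over the list alone (median 0.37), namely Flt4 at 1.34 ± 0.27 and Lyve1 at 1.22 ± 0.34, and with DESeq2 neither Bmx nor Lyve1 passed. With the length and GC trend removed 1 venous marker rose and 0 fell (median -0.04), and Flt4 (0.79) no longer passed. In the Notch pathway 6 of 18 rose and 1 fell (7 and 1 adjusted over the list alone, with a median of 0.31), but 2 and 2 with the length and GC trend removed (median 0.03). Notch3 stood at 1.48 ± 0.26 and the ligand Dll1 at -2.70 ± 0.72, and at 0.76 and -2.95 with the trend removed.

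The list of endocardial-to-mesenchymal transition and cushion genes had 8 of 38 higher and 6 lower (10 and 11 adjusted over the list alone), with a median of -0.15, but 5 and 9 with the length and GC trend removed (median -0.44). Its higher members included Zeb1 at 1.21 ± 0.22, the cushion proteoglycan Vcan at 0.87 ± 0.18 and Tgfb1 at 1.00 ± 0.22. The 6 lower members were Wnt4 and 5 transcription factor genes, Twist1 (-0.93 ± 0.23), Sox9 (-0.81 ± 0.20), Foxc1 (-1.19 ± 0.32), Msx2 (-1.08 ± 0.28) and Msx1, the last with 3 and 3 reads against 33, and Twist1, Foxc1 and Msx2 did not pass with DESeq2. In the Wnt pathway 6 of 28 rose and 4 fell (6 and 5 adjusted over the list alone; median 0.03), but 3 and 4 with the length and GC trend removed (median -0.13). Besides Wnt4 the secreted inhibitor Dkk1 fell, with 5 and 10 reads against 67 (-3.18 ± 0.56), while Dkk3 rose by 1.88 ± 0.25 and the receptor gene Fzd1 by 1.81 ± 0.28. In the BMP and TGF-beta pathway 11 of 29 rose and 2 fell (11 and 3 adjusted over the list alone, with a median of 0.31), with Bmp10 and Bmp6 (2.07 ± 0.32) higher and Id2 (-1.38 ± 0.20) lower. With the length and GC trend removed 9 of these pathway genes rose and 1 fell (median 0.11). Camera with a preset correlation called the BMP and TGF-beta list at adjusted p = 0.0305, against adjusted p = 0.937 with an estimated correlation.

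All 11 megakaryocyte and platelet markers rose, also adjusted over the list alone, with a median of 2.40, or 2.51 and 1.83 in the 2 null libraries. The chemokine genes Pf4 and Ppbp, whose products are stored in platelet granules, rose by 2.40 ± 0.31 and 2.77 ± 0.39, the integrin gene Itgb3 by 2.11 ± 0.28 and the thrombin receptor gene F2rl2 by 2.73 ± 0.34. The list was called by camera with a preset correlation at adjusted p = 5.81e-08, against adjusted p = 0.937 with an estimated correlation. Primitive erythroid markers had 2 of 21 higher and 0 lower, also adjusted over the list alone. These were the haem synthesis enzyme Cpox (0.81 ± 0.20) and the beta-spectrin gene Spnb1 (0.88 ± 0.23), while the list median was -0.41, or -1.43 in Sox7-null 1 and 0.23 in Sox7-null 2. The embryonic globin gene Hbb-y had a log2 fold change of -0.53 ± 0.36 (0.080 with the length and GC trend removed), and haemoglobin genes held 0.459%, 1.43% and 1.32% of gene counts in Sox7-null 1, Sox7-null 2 and the wild type. Among 14 macrophage and leukocyte markers 3 rose and 1 fell, also adjusted over the list alone. Laptm5 (1.71 ± 0.45), Fcer1g (2.07 ± 0.56) and Coro1a (1.38 ± 0.38) were higher and Lyz2 (-1.39 ± 0.36) lower, and the list median of 1.07 was 1.30 in Sox7-null 1 and -0.31 in Sox7-null 2. With DESeq2, Spnb1, Fcer1g, Coro1a and Lyz2 did not pass, nor did Laptm5 and Fcer1g with limma-voom.

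Markers of foregut endoderm and liver bud fell. Of 17 tested, 10 fell and 1 rose, also adjusted over the list alone, and the median was -2.40, but 0.20 at a minimum mean of 5 CPM, which leaves out members with few reads. Besides Afp and Ttr, the apolipoprotein gene Apoa2 fell, at -3.24 ± 0.67, and albumin (Alb) had 0 reads in the null libraries and 23 in the wild type, at least 15.8-fold lower against a floor of 3 counts over the group. The pioneer factor gene Foxa1 had 3 reads in the null libraries and 26 in the wild type, 17.8-fold lower (95% exact interval 5.46 to 92.0), and the retinol carrier Rbp4 was the member that rose (1.08 ± 0.32), though not with DESeq2. Camera with a preset correlation called this list at adjusted p = 2.05e-05, against adjusted p = 0.937 with an estimated correlation. Of 6 surface ectoderm markers 2 fell and 0 rose, also adjusted over the list alone (Epcam -2.40 ± 0.67, Perp -0.83 ± 0.20; median -0.85, but -0.37 without Sox7-null 1 and -1.65 without Sox7-null 2). In 6 extraembryonic and placental markers 0 passed in either way (median -0.55). Of 8 neural tube and neuron markers 2 rose and 1 fell, also adjusted over the list alone (Nes 0.84 ± 0.18, Sox3 1.79 ± 0.42, Elavl4 -1.04 ± 0.31; median 0.23, or 0.55 in Sox7-null 1 and -0.28 in Sox7-null 2). Of 8 neural crest markers 1 rose (Ets1, 0.66 ± 0.20) and 0 passed adjusted over the list alone (median -0.11, or 0.10 in Sox7-null 1 and -0.10 in Sox7-null 2), and Ets1, Sox3 and Elavl4 did not pass with DESeq2. No retina marker of 3 passed (median -0.33), though 1 rose adjusted over the list alone. Of 20 retina markers in the files these 3 alone passed the filter for low counts, against 39 of 39 sarcomere and contractile genes. These shares argue against retinal organoids as the source. Skeletal muscle and somite markers (3 tested, median 0.69) and genes of the Y chromosome and X inactivation (5 tested, median 0.42, or -0.52 in Sox7-null 1 and 0.95 in Sox7-null 2) had 0 past the test either way.

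Of 34 extracellular matrix genes 19 rose and 1 fell (20 and 3 adjusted over the list alone), with a median of 0.94, or 1.15 and 0.64 in the 2 null libraries. With the length and GC trend removed 15 rose and 2 fell (median 0.54). The matricellular genes Ctgf and Cyr61 rose by 2.53 ± 0.25 and 1.79 ± 0.20, the collagen crosslinker Loxl2 by 1.86 ± 0.23 and perlecan (Hspg2) by 2.10 ± 0.26, while Lum fell, with 7 reads in the null libraries against 23. With the trend removed Ctgf, Cyr61, Loxl2 and Hspg2 stood at 2.60, 1.85, 1.54 and 1.19. Cell cycle, ribosomal protein and oxidative phosphorylation genes past the test were mostly lower. Among 33 cell cycle genes 9 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.30), with the nucleotide synthesis genes Rrm2 at -1.43 ± 0.22 and Tyms at -1.39 ± 0.23, Pcna at -1.04 ± 0.20 and Ccne1 at -1.40 ± 0.28. Of 40 ribosomal protein genes 23 fell and 1 rose (29 and 1 adjusted over the list alone, median -0.44), with Rpl27 at -0.92 ± 0.14 and Rplp1 at -0.76 ± 0.13. Once the length and GC trend was removed 3 fell and 2 rose, and neither Rpl27 (-0.49) nor Rplp1 (-0.24) passed. Pseudogene copies leave single members of that list uncertain. Of 32 nuclear genes of oxidative phosphorylation 11 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.35), with Cycs at -0.97 ± 0.15 and Cox7a2 at -0.92 ± 0.16. Once the length and GC trend was removed 3 fell and 2 rose (median -0.01), and Cox7a2 (-0.36) no longer passed. Replication-dependent histone genes, which also share reads between copies, had 1 of 13 lower and 0 higher, also adjusted over the list alone (Hist1h1a, with 2 reads in the null libraries against 17; median -1.03, but 0.39 at a minimum mean of 5 CPM). Camera with a preset correlation called the matrix, cell cycle, ribosomal protein and oxidative phosphorylation lists, with adjusted p = 0.937 for each with an estimated correlation.

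**Figure D2:**
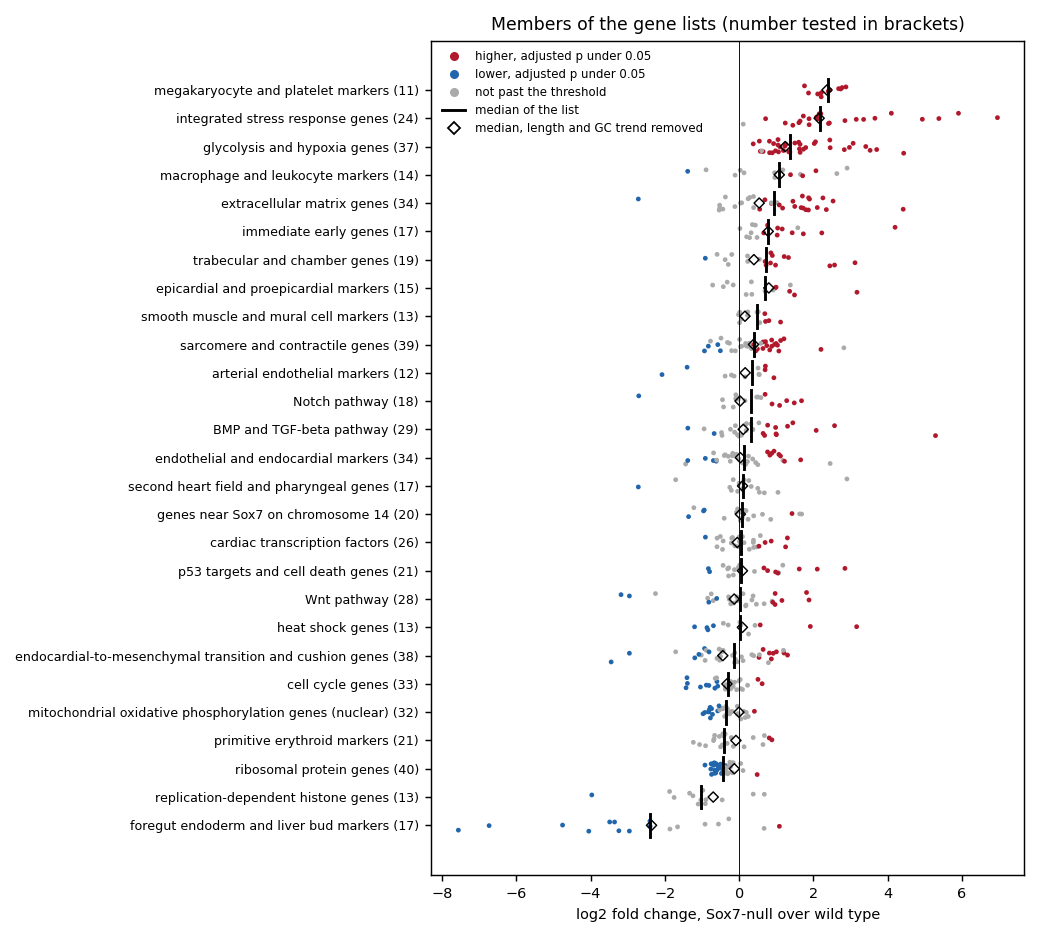
Log2 fold changes (Sox7-null over wild type, horizontal axis) of the tested members of the gene lists with at least 10 tested genes, 1 point per gene, in red or blue where the adjusted p was under 0.05, with a bar at the list median and a diamond at the median once the trend on transcript length and GC was removed. Platelet, stress response and glycolysis lists have medians of 2.40, 2.18 and 1.37, the foregut list has -2.40, and for ribosomal protein genes the median moves from -0.44 to -0.13.

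Several of these groups moved together with transcript length. Across genes, which are not independent replicates, the log2 fold change was larger at greater length (Spearman rho 0.302) and GC content (0.165), and the difference of Sox7-null 1 from Sox7-null 2 followed length too (0.204). Among genes split into 10 groups by length, the shortest had a median of -0.48, with 68 higher and 406 lower, and the longest had 0.31, with 267 higher and 40 lower. With this trend removed, in a fit chosen after seeing the data, 3 of 40 ribosomal protein genes fell and 2 rose (median -0.13), and 3 of 32 oxidative phosphorylation genes fell and 2 rose (median -0.01). Matrix genes then had 15 higher and 2 lower (median 0.54), trabecular genes 6 and 2 (0.40), sarcomere genes 12 and 1 (0.39), BMP and TGF-beta genes 9 and 1 (0.11), smooth muscle markers 2 and 1 (0.16), Notch genes 2 and 2 (0.03) and endothelial markers 3 and 5 (0.03). Cushion genes had 5 higher and 9 lower (-0.44), cell cycle genes 0 and 10 (-0.33) and foregut markers 1 and 9 (-2.36). Glycolysis genes kept 36 higher and 0 lower (median 1.24), stress response genes 23 and 0 (2.15) and platelet markers 11 and 0 (2.36). Immediate early genes had 7 and 0 (0.78), p53 targets 8 and 1 (0.09), heat shock genes 3 and 4 (0.09), epicardial markers 4 and 0 (0.80), macrophage markers 3 and 0 (1.08), erythroid markers 1 and 1 (-0.09), venous markers 1 and 0 (-0.04), neural tube markers 1 and 0 (0.12), neural crest markers 0 and 0 (-0.11), surface ectoderm markers 0 and 1 (-0.88) and the neighbours of Sox7 1 and 2 (0.03). Some calls ended there with a fold that had moved toward 0 by more than its SE, from -0.92 to -0.36 for Cox7a2, -0.92 to -0.49 for Rpl27, -0.76 to -0.24 for Rplp1, -0.57 to -0.07 for Myl2, -0.93 to -0.60 for Pln, 0.88 to 0.21 for Spnb1, 0.84 to 0.34 for Nes, 1.34 to 0.79 for Flt4, -1.39 to -1.01 for Lyz2, -1.36 to -0.97 for Pinx1 and -0.83 to -0.61 for Perp. Others ended with a fold within 1 SE of its first value, at -0.90 for Elavl4, 0.50 for Ets1 and -2.45 for Lum. Removing the trend cannot separate a bias by length or GC from a real change shared by genes of similar length or GC.

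**Figure D3:**
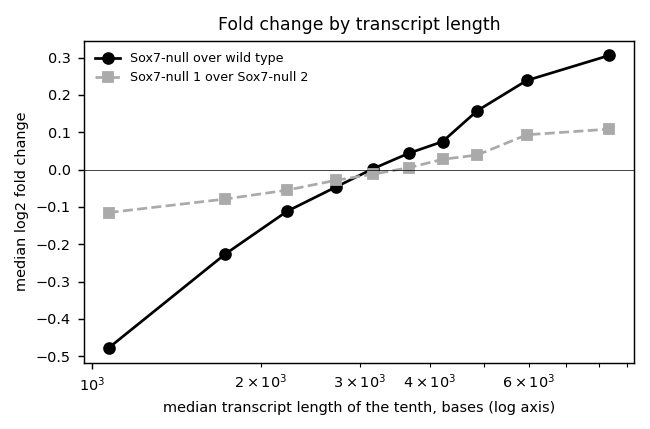
Median log2 fold change (vertical axis) of the tested genes in 10 groups by transcript length (horizontal axis, median length of the group in bases, log scale), for Sox7-null over wild type in black and for Sox7-null 1 over Sox7-null 2 in grey. The black line runs from -0.48 in the shortest group to 0.31 in the longest, and the grey line from -0.12 to 0.11.

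Genes that neighbour Sox7 on chromosome 14 were examined because a targeted allele can carry linked strain variants. Of 20 tested, 1 rose and 3 fell (1 and 2 adjusted over the list alone; median 0.07). Zfp395 rose by 1.42 ± 0.25, while Pinx1 (-1.36 ± 0.33) and Fbxo16 (-0.96 ± 0.32) fell, and so did Tmem20, which does not lie near Sox7 in the reference annotation. Of the 18 tested members that lie within 5 Mb of Sox7, 1 rose and 2 fell, and neither Pinx1 nor Fbxo16 passed with DESeq2.

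The libraries differed in makeup as well as genotype. Of all reads in the files, 79.2% and 77.6% were assigned to genes in the null libraries and 64.1% in the wild type, and 10.4%, 11.6% and 22.3% were not uniquely aligned. The ribosomal RNA gene Rn45s held 0.654%, 0.926% and 2.08% of gene counts. The widest 95% Clopper-Pearson half-width of these shares was 0.0203 percentage points, which covers counting error only. Sox7-null 1 lay further from the wild type than Sox7-null 2, with an SD of log2 differences across genes of 0.816 against 0.624, and 0.386 between the null libraries. At least 2-fold differences in both null libraries, at a mean of 5 CPM or more, were found for 503 genes that were higher and 180 that were lower. With scaling and mean CPM kept from all 3 libraries, Sox7-null 1 taken by itself gave 975 and 662, and Sox7-null 2 gave 527 and 203. With both computed anew from the 2 libraries left, the counts were 964 and 671, and 471 and 214.

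**Figure D4:**
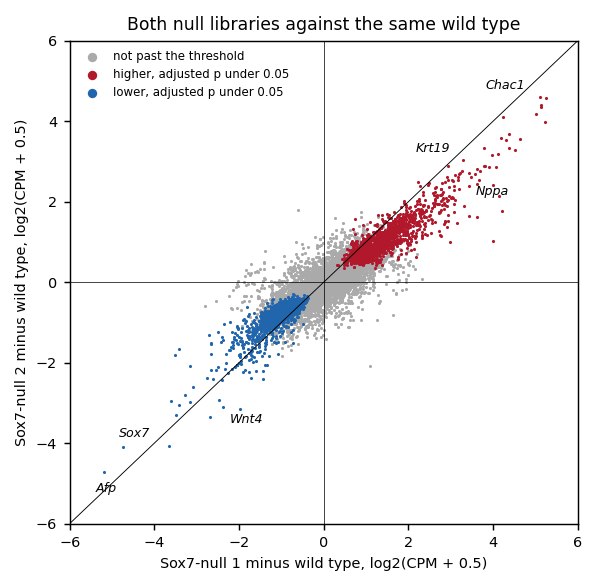
Difference of each gene from the wild-type library in Sox7-null 1 (horizontal axis) and Sox7-null 2 (vertical axis), as log2(CPM + 0.5), with genes at an adjusted p under 0.05 in red or blue and the diagonal drawn. Of the 2874 called genes, 2551 lie closer to 0 in Sox7-null 2 than in Sox7-null 1.

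With a single wild-type library, the spread came from the 2 null libraries alone, and the calls also rested on the filter for low counts. Without that filter edgeR called 0 genes (4113 at an unadjusted p under 0.05, smallest adjusted p = 0.122), edgeR with legacy=FALSE 0 (3963) and limma-voom 0 (3837). DESeq2 called 1649, but its own default filter on mean count stayed on, so its calls are not a like comparison. With the filter DESeq2 called 941 higher and 721 lower and glmTreat, against a fold of 1.5, 481 and 219.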

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

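The tests without a filter other than edgeR's default, and the fit with the length and GC trend removed, were chosen after the results were seen. Counts of called genes (1508 higher, 1366 lower) stayed within 1.5 times under DESeq2 size factors (1543 and 1457), a minimum of 5 CPM (1219 and 1071), removal of haemoglobin and ribosomal RNA genes (1511 and 1375), limma-voom (1252 and 1297), edgeR with legacy=FALSE (1408 and 1319) or robust=TRUE (1455 and 1377) and the length and GC fit (1047 and 1028, of which 1748 in all were also called in the fit of the report, each in the same direction). They moved further with the DESeq2 Wald test (941 and 721, all 1662 shared), which called 110 of 196 simulated changes where limma-voom called 139 (the cause was not tested), and with glmTreat against a fold of 1.5 (481 and 219), which asks for a larger change. Without the filter, edgeR called 0 higher and 0 lower (4113 at an unadjusted p under 0.05), legacy=FALSE 0 and 0 (3963) and limma-voom 0 and 0 (3837). DESeq2, whose own default filter on mean count stayed on, called 967 and 682. In the edgeR fit 17242 genes were then tested and the prior degrees of freedom were 3.23 in place of 11.8. Genes at least 2-fold higher and lower in both null libraries numbered 503 and 180. Leaving out Sox7-null 1 gave 471 and 214 and leaving out Sox7-null 2 gave 964 and 671, where scaling and mean CPM were computed anew from the 2 libraries left. In runs added after these were seen, keeping both from all 3 libraries gave 527 and 203, and 975 and 662. Keeping the scaling alone gave 473 and 217, and 967 and 671, so the drop below 503 came with the mean CPM over 2 libraries.

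Of the genes named in the text, Hbb-y, which did not pass the test, reversed from -0.53 to 0.080 with the length and GC fit (the cause was not tested). Over named genes and settings, 1353 values kept their side of the threshold or moved within the spread, 52 moved, 203 fell short of the threshold (148 of them with no filter, 24 with the length and GC fit, 25 with DESeq2, 4 with limma-voom and 2 at 5 CPM) and 1 passed it newly. List medians reversed at a minimum of 5 CPM for foregut and liver markers (0.20) and histone genes (0.39), a setting that tests fewer of their genes. Leaving out one null library, the medians ran from -0.045 to 1.18 for epicardial, from -1.44 to 0.23 for erythroid and from -0.67 to 1.81 for macrophage and leukocyte markers, so the library left out sets their sign. It also did for neural tube (-0.34 to 0.60), sex-linked (-0.56 to 1.00), neural crest (-0.12 to 0.10) and cardiac transcription factor (-0.026 to 0.13) lists, whose medians lay inside the percentiles of random lists. Wnt and heat shock medians, 0.03 and 0.02, were below 0 whichever null library was left out. With 1 wild-type library, no leave-out tests that library, and genes with few reads carry wide intervals at this depth.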

Other observations

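All gene lists in this paragraph and the next were drawn up after the results were seen, as were the tests below on heat shock genes, single null libraries, erythroid markers and leukocytes (in both null libraries and in Sox7-null 1), while those on length and GC, the lone wild-type library, liver, yolk sac and endoderm genes were set before their results were seen. Basement membrane genes rose together, with 13 of 17 higher and 0 lower (13 also adjusted over the list alone) and a median log2 fold change of 1.44. Among them the collagen IV genes Col4a1 and Col4a2 rose by 1.90 ± 0.29 and 2.26 ± 0.28 and nidogen (Nid1) by 1.70 ± 0.29. Of the 17, 10 also stand in a list of the report, and with the length and GC trend removed 10 rose and the median was 0.80. Of 14 collagen-modifying enzymes 9 rose and 0 fell (median 1.34, and 1.08 with the trend removed), including the lysyl hydroxylase Plod2 at 2.04 ± 0.24 and the prolyl hydroxylase P4ha1 at 1.64 ± 0.21, and 4 stand in a list of the report. Of 20 cytosolic aminoacyl-tRNA synthetases 9 rose and 0 fell (median 0.45, and 9 and 0 with the trend removed), with Sars at 1.64 ± 0.20 and Aars at 1.20 ± 0.19, and 2 of the 20 stand in a list of the report. Col4a1 and Nid1 did not pass with DESeq2.

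Mitochondrial ribosomal protein genes were lower, with 19 of 25 that fell and 0 that rose (median -0.82, edgeR adjusted p = 0.000998 for Mrpl33 at -1.45 ± 0.21). With the length and GC trend removed 12 fell and the median was -0.59. Of 10 class I and class II histocompatibility genes 3 rose and 0 fell (median 0.68), H2-Ab1 at 2.68 ± 0.25 with 1371 and 1112 reads against 189, H2-K1 at 4.24 ± 0.47 with 704 and 345 against 27, and H2-Q2 at 1.51 ± 0.42, which did not pass with DESeq2 or limma-voom, and 4 rose with the trend removed. Paralogs of this family share reads, and haplotypes that differ between strains can change how many of them align, so these values are uncertain. Of 20 imprinted genes 8 rose and 4 fell (median 0.39), but 3 and 2 with the trend removed (median 0.25). H19 stood at 0.97 ± 0.15 and Phlda2 at -1.76 ± 0.47, and the call of Phlda2 ended with the trend removed (-1.37) and with DESeq2. Of 22 cholesterol synthesis genes 0 rose and 2 fell (one of them Idi1, at -0.84 ± 0.21; median -0.27, with 0 and 1 once the trend was removed), of 9 interferon-stimulated genes 0 passed (median 0.45, with 1 higher and 1 lower once it was removed), and of 16 growth-regulated translation genes outside the ribosome 3 rose and 3 fell (median -0.036, with 4 and 0 once it was removed). Of 14 genes of a wider liver list 10 fell and 1 rose, with or without the trend, and 9 of the 14 stand in a list of the report.

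Glycolysis and hypoxia genes and integrated stress response genes rose in the Sox7-null libraries. After a loess trend on transcript length and GC was taken from the fold changes, the smaller of their medians was 1.19. This argues against such a trend as the whole cause. The smallest of the 4 medians in single null libraries was 1.27, so both libraries showed the rise against the same wild type. Most members had passed a test that nearly requires the null libraries to agree. A rise in a single null library could therefore hardly have appeared here. General stress of handling was read from the heat shock list, whose median was 0.018. That value met the bound first set against this explanation, but 3 of its members rose and 4 fell, so after it was seen the test was taken to decide nothing. Immediate early genes rose, with 9 of 17 higher and 0 lower (median 0.77), so stress of handling stays open. Setting the wild type alone gave 2874 calls. Setting a null library alone gave at most 0 (580 and 20 at an unadjusted p under 0.05 in edgeR). With a null library alone, the spread comes from the other null library and the wild type, so calls could hardly arise. These counts are therefore no fair contrast, and 3 splits are too few to exclude chance. A wild-type library that deviates for another reason cannot be told apart from the genotype because there is 1 such library.

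Megakaryocyte and platelet markers rose by a median of 2.40. More blood of every kind is argued against by the erythroid markers, whose median was 0.23 in the null library where it was higher. More leukocytes of every kind in both null libraries are argued against by their median of -0.31 in Sox7-null 2, with an SD of 0.813 over members. Of the 4 leukocyte markers past the test, Laptm5, Fcer1g and Coro1a were higher there (0.94, 1.37 and 0.93) and Lyz2 lower (-1.50). A rise of some leukocytes therefore stays open. In Sox7-null 1 the leukocyte median was 1.30 against a platelet median of 2.51. The SD over the leukocyte markers was 0.938, so that more leukocytes stay open there. To the tests over both libraries a condition on the spread between list members was added after the values were seen, which left their outcomes as they were. Both null libraries showed the rise against the same wild type, as the smaller of the 2 medians was 1.83. All of these markers had passed a test that nearly requires the null libraries to agree. A rise in a single null library could therefore hardly have appeared here. An effect of the genotype was not tested, and with 1 wild-type library a deviation of that library stays open too.

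Foregut endoderm and liver bud markers fell, with Afp and Ttr at 271 and 187 reads in the wild type. Of 14 liver genes with at least 10 reads 12 were highest in the wild type. That list was drawn up after the results were seen, and 9 of its genes stand in a list of the report. The 33.3% that chance gives is therefore no fair measure for it. The bound of 15 genes set beforehand could not be reached either, so this test decides nothing about liver bud tissue in that tube. Visceral yolk sac tissue in the wild-type tube may have contributed, since 4 of 4 of its genes (Cubn, Amn, Lrp2 and Rhox5) were highest there, though none passed the threshold (edgeR adjusted p from 0.0808 to 0.677) and Rbp4, which liver and yolk sac both make, rose in the null libraries. These 4 yolk sac genes had log2 fold changes from -0.92 to -0.38, far smaller falls than those of Afp (-6.73) and Ttr (-4.75). For less endoderm of every kind, 5 of 5 detected endoderm genes were lower in both null libraries, but all 5 are members of the foregut list, so after the value was seen the test was taken to decide nothing. Both explanations stay open, as does an effect of the genotype on endoderm, which was not tested.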
